A study of Mus musculus with 26 samples.

How the data were processed

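All values start from the peak lists deposited for 26 libraries, of which 4 are input. Per the labels, cells were given 50 ng/ml doxycycline for 18 h and 500 ng/ml LPS for 1 h, and HA ChIP used 2 mM DSG before 1% formaldehyde. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.1.0 and peaks were called with HOMER, whose version is not given. Per the file headers, HA peaks were called in factor style at an FDR of 0.001 and 4 times the local 10 kb, and Pol II and H3K27ac regions in histone style at a Poisson p of 0.001. Per the file headers, no input was used in calling, and the option that turns off the local filter was absent in 3 H3K27ac libraries (untreated GFP replicate 1, GFP LPS replicate 1 and untreated Nur77 replicate 1). The header of untreated HA replicate 3 names tags not marked as filtered, unlike those of the other ChIP libraries, so this difference falls on the untreated side only.

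The signal is the normalized tag count as deposited, which the authors' software scales to 10 M mapped tags. The deposited score, the deposited focus ratio (a fraction), the deposited local and clonal fold changes (ratios) and the deposited p-value against local signal were read and not tested. The score of a stitched region is per the file headers that of one putative peak and did not follow its tags, so regions were ranked by the deposited normalized tags. The plan made before the data were examined named a test for whole counts. The deposited values are not whole counts, so limma 3.58.1 was used instead, with a trend, on log2 of the normalized tags plus 1. Counting tools were not run on these values.

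The choice of contrasts, the gene lists, the naming rule, the test threshold and the other settings listed beforehand were made before the data were examined. Peaks of one target were merged where they shared at least 1 bp, and a region's value is the sum of its deposited normalized tags. A region called in one group only had a peak in all libraries of that group and in none of the other. A region was tested where all libraries of its target had a peak. Libraries were scaled by trimmed means of M-values, with 30% of M-values and 5% of A-values trimmed. Scaling factors ran from 0.57 to 1.33 for HA, where replicate 3 had 0.574 and 0.624, from 0.89 to 1.23 for Pol II and from 0.84 to 1.17 for H3K27ac. P-values were adjusted by the Benjamini-Hochberg method per comparison, and an FDR of 0.05 was used throughout. Group values in the text are scaled, except those of regions called in one group or one line only, which are means of the deposited normalized tags, and covered length is the mean summed length of called peaks in kb.

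A gene was given to a region that overlapped its span plus 1 kb, and otherwise the nearest gene within 50 kb was named as near. The list of genes holds no strand, so promoters and transcription start sites were not used. Named regions were the largest called changes, at most 10 per direction, the 3 members with the smallest p of each list, the 10 HA regions with the highest signal, 5 group-only regions per direction and all regions of Nr4a1. Regions over an input peak were not named, and those over a region called in input were named and tested. Among others, named regions over Batf, Fos, Atf3, Rhob, Gpnmb, Calcrl and the lysozyme genes overlapped a region called in input in at least one assay. The fixed lists were: AP-1 family, immediate-early genes outside AP-1, LPS-induced cytokines and chemokines, NF-kB pathway and feedback, interferon response, macrophage lineage, lysosome and lipid handling, TCA cycle and mitochondrial metabolism, housekeeping, and genes of other cell types. In the lists each gene was represented by its lead region only, the tested region over it with the highest mean normalized tags. For HA and H3K27ac a region near the gene was used where none overlapped. Counts and tests of lists therefore leave out the other regions of these genes. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with limma's fry. Lists with fewer than 3 regions were not tested.

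Depth and agreement of replicates were as follows. Peaks held 7.54 to 17.0% of tags for HA, 53.5 to 64.9% for Pol II and 47.5 to 59.5% for H3K27ac. Replicates correlated with a Pearson r from 0.746 to 0.928 for HA, 0.938 to 0.955 for Pol II and 0.979 to 0.986 for H3K27ac, across regions. Deviations from group means paired by replicate number in HA (correlations 0.48 to 0.83) and Pol II (0.35 to 0.63), and not in H3K27ac (-0.10 to 0.09). Replicate number was therefore added as a block as an alternative, not as the default, because the labels do not name batches.

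In a self-test libraries were simulated from the region means, mapped tags and spread of the data, with known changes in 100 regions per fold, 200 per run. The limma steps were then repeated. Noise was drawn independently per library, without pairing by replicate number. Far fewer regions changed than LPS changed in H3K27ac, so recovery in the data may differ. Of the HA regions changed by LPS (11234 tested) 23% of 2-fold and 98% of 4-fold changes were recovered. For Pol II (17081 tested) they were 17 and 79% for LPS in GFP cells, 25 and 84% for LPS in Nur77 cells, 20 and 81% for the lines untreated, 22 and 78% for the lines after LPS, and 2 and 40% for the interaction. For H3K27ac (27094 tested) they were 70 and 98%, 75 and 97%, 76 and 99%, 79 and 95%, and 61 and 89% for the same comparisons. No change was called with the wrong sign. Unchanged regions were also called, 4 for HA, 3 to 8 per run for Pol II and 6 to 19 per run for H3K27ac. Scripts ran in R 4.3.3 with GenomicRanges 1.54.1 and data.table (1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

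Left out were the planned motif test, which needs a genome sequence, and any test of raw reads, which were not analysed here. The result for a gene withheld for evaluation was also left out of the text.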

Results

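The series mapped HA-tagged Nur77, RNA polymerase II (Pol II) and acetylated lysine 27 of histone H3 (H3K27ac) by ChIP-seq in RAW264.7 cells, a mouse macrophage line. One stable line made HA-Nur77 and another made GFP when doxycycline was given, and each line was left untreated or given LPS for 1 h. The data hold 6 HA libraries of Nur77 cells (n = 3 per condition), 8 Pol II and 8 H3K27ac libraries (n = 2 per line and condition) and 4 input libraries. Depth was 6.41 to 18.2 M mapped tags (M for mega) for HA, 11.9 to 23.1 M for Pol II, 22.3 to 28.4 M for H3K27ac and 14.02 to 23.4 M for input. In HA replicate 3 the called peaks were 342 and 427 bp wide, against 826 to 1017 bp in the others, and the fragment length given for untreated Nur77 Pol II replicate 1 was 1550 bp, against 174 to 318 bp in the others. The labels do not say that replicates came from separate cultures, so they may be technical. Values below are normalized tags per 10 M mapped tags, summed over the peaks of a region and scaled between libraries, with the SD over libraries. Values of regions called in one group only are not scaled. A region was tested where every library of its target had a peak, which held for 11234 of 42505 HA, 17081 of 46133 Pol II and 27094 of 77715 H3K27ac regions. Coordinates are on mm10.

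**Figure D1:**
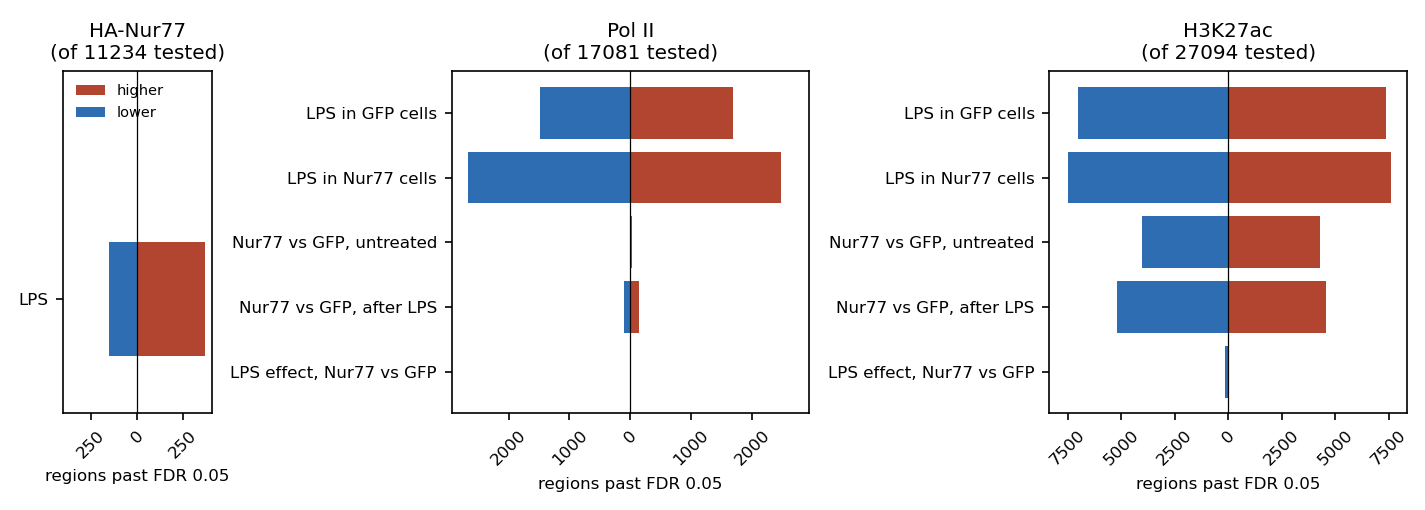
Number of regions past an FDR of 0.05 per comparison (x axis, counts) for HA-Nur77, Pol II and H3K27ac. Bars to the right are regions higher in the condition named first (LPS, or Nur77 cells), bars to the left are lower, and the last pair of bars is the difference of the LPS effect between lines.

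The first question was whether LPS changed where HA-Nur77 sat. The largest gain was inside Nfkb1, the gene of the NF-kB subunit p50 (chr3:135670180-135671196, mm10), at 309 ± 123 (SD, n = 3) normalized tags after LPS and 25.0 ± 10.4 (SD, n = 3) before. Next came a site in Gm47922, at 294 ± 106 against 33.5 ± 10.7 (SD, n = 3). Other large gains were near Lad1, in Mtmr7, in Tgm2, which encodes a transglutaminase, in Slpi, which encodes a protease inhibitor, and in Cd44, the hyaluronan receptor gene. The site in Tgm2 rose from 35.6 ± 9.01 to 227 ± 38.6 (SD, n = 3), and the site in Cd44 from 25.2 ± 4.41 to 129 ± 21.1 (SD, n = 3). Signal fell in Maco1, from 143 ± 35.8 to 29.6 ± 6.78 (SD, n = 3), in the zinc transporter gene Slc39a11, in the retinoblastoma gene Rb1, in Serinc3 and in the histone deacetylase gene Hdac4. Peak width was set per library, and its mean was 0.710 kb after LPS and 0.757 kb before. With tags per bp 514 regions passed.

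**Figure D2:**
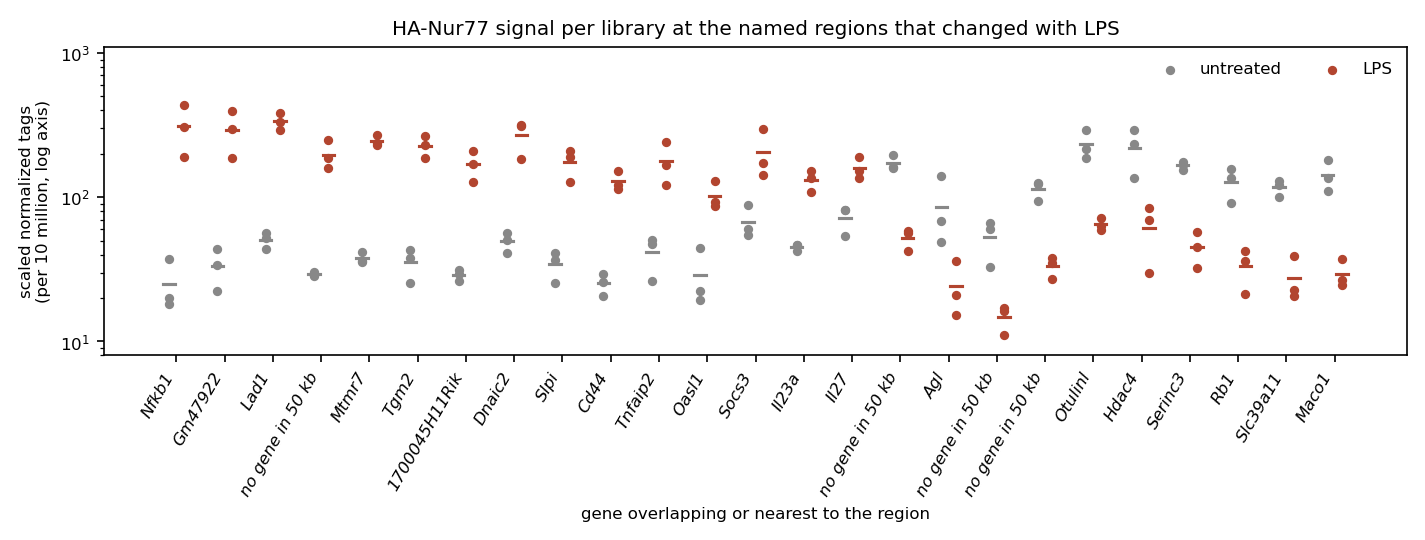
HA-Nur77 signal at the named regions that passed the test, with the overlapping or nearest gene on the x axis and scaled normalized tags per 10 M on a log y axis. Each point is one library, grey for untreated and red for LPS (n = 3 each), and short bars are means.

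Among the fixed lists, which held few of the 369 regions that rose, changes were as follows. Of 20 NF-kB pathway regions 4 rose and none fell, among them Nfkb1 with a log2 change of 3.56 ± 0.37 (SE), Tnfaip2 at 2.06 ± 0.35 and a site near Socs3, a feedback inhibitor of cytokine signalling, at 1.54 ± 0.33. The region in Tnfaip2 also overlapped a region called in input. Adjusted over the list alone, 10 NF-kB regions rose and 1 fell, the median was 0.72, and limma's camera test gave an adjusted p = 1.7e-05. That call was lost with an adjusted p = 0.089 with an estimated correlation. Among 11 cytokine and chemokine regions, those in Il23a (1.52 ± 0.26) and near Il27 (1.14 ± 0.28) rose, 4 rose when adjusted over the list alone, and camera gave an adjusted p = 0.0051, or an adjusted p = 0.13 with an estimated correlation. The fry test, which asks whether a list moves on balance in one direction without comparing it with other genes, gave an adjusted p = 0.0067 for the NF-kB list and 0.0081 for the cytokine list. Of 5 interferon regions 1 rose, in Oasl1 (1.87 ± 0.34), and 2 rose adjusted over the list alone. None of the lead regions of the AP-1 family list passed. These 5 regions had a median of -0.22 and a mean of 0.11, and camera pointed up with an adjusted p = 0.85. The values were 0.76 ± 0.29 in Batf, 0.64 ± 0.27 near Atf3 and -0.33 ± 0.31 near Fosl2. No member passed among 15 immediate-early, 16 macrophage, 12 lysosome and lipid, 8 TCA cycle, 4 housekeeping or 3 silent control regions. Medians and means differed in sign for the TCA cycle (0.03 and -0.06), lysosome (0.01 and -0.10) and housekeeping (-0.05 and 0.00) lists. These lists without a call rest on the fit that leaves out the pairing of replicates. With replicate number as a block, 2 AP-1 regions rose, in Batf (adjusted p = 1.2e-04) and near Atf3 (adjusted p = 3.2e-04). The block also called 2 immediate-early regions higher, 6 macrophage regions higher and 3 lower, 2 lysosome regions higher and 3 lower, 1 TCA cycle region higher and 2 lower, and 1 housekeeping and 1 silent control region lower. NF-kB regions then went 12 up and 1 down and cytokine regions 7 up and 1 down. Of the lists without a call only the macrophage list then passed fry (adjusted p = 0.035), and none passed camera.

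In all, limma called 520 of the 11234 HA regions, 369 higher and 151 lower, at an FDR of 0.05. With replicate number as a block the count was 4552, with 2304 higher and 2248 lower, and without scaling factors it was 6, all higher. No region passed without untreated replicate 1 or without LPS replicate 1, 83 passed without untreated replicate 3, 166 without LPS replicate 3 and 0 without both replicate 3 libraries. Without both but with the block 4046 passed, including all 520, so without replicate 3 the calls were lost only in the fit that leaves out the pairing of replicates. The strongest sites did not pass in the fit that leaves out the pairing of replicates. Near Mcl1, an anti-apoptotic gene, signal was 1459 ± 389 after LPS and 1371 ± 116 before (SD, n = 3). Near Pmaip1, a pro-apoptotic gene, it was 934 ± 311 and 1133 ± 398 (SD, n = 3). In Usp32 it was 747 ± 38.6 after LPS and 662 ± 37.0 before (SD, n = 3).

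As peaks, 11234 HA regions were called in all 6 libraries, 1962 in all 3 LPS libraries but in no untreated one, and 278 the other way round. With lists of equal length the counts were 1081 and 589. The other ways of splitting the 6 libraries gave at most 492 regions for one side. The 1962 regions exceeded this count, and the 278 called before LPS only did not. These splits were made with full lists only. The strongest site called after LPS only lay in the chemokine gene Ccl4 (chr11:83665118-83666159, mm10; 524 ± 461, SD, n = 3), and others lay in Ptprj (252 ± 136, SD, n = 3) and near Itpkb (225 ± 110, SD, n = 3). Sites called before LPS only included one in Clec5a and Olfr460 (104 ± 72.1, SD, n = 3) and one in Iqgap1 (103 ± 59.3, SD, n = 3).

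The next question was where LPS changed Pol II in GFP cells. The largest gain was over Acod1, which makes itaconate, together with Gm41235 and Gm41236 (chr14:103045722-103064029, mm10). Signal there was 8180 ± 3399 after LPS and 110.3 ± 4.73 before (SD, n = 2), over 16.2 and 1.48 kb, or 504 and 74.3 tags per kb. The region of the chemokine gene Cxcl10 and Art3 rose from 53.2 ± 1.91 to 2328 ± 568 (SD, n = 2), over 1.86 and 11.03 kb, a log2 change of 5.40 ± 0.28. The chemokine genes Cxcl1 and Cxcl2 share a region that rose by 4.48 ± 0.30, from 82.9 to 1412 tags per kb over 12.9 and 17.1 kb. Cd83, a marker of activated antigen-presenting cells, rose by 5.27 ± 0.30, with a change in covered length from 6.49 to 26.9 kb. Ttc39a (-3.40 ± 0.38), Cytip (-3.34 ± 0.31) and the calcium channel gene Cacna1d (-3.25 ± 0.40) fell.

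By group, 11 of 12 cytokine and chemokine regions rose and none fell, 12 when adjusted over the list alone, with a median log2 change of 3.17. Camera gave an adjusted p = 2.4e-11, and an adjusted p = 0.027 with an estimated correlation, which was lost with the block (adjusted p = 0.13 with an estimated correlation). Of 27 NF-kB regions 21 rose, including Traf1 (3.94 ± 0.20) and Nfkb2, shared with Psd (2.23 ± 0.18), and 25 rose adjusted over the list alone. Of 23 immediate-early regions 11 rose and 1 fell (13 and 1 adjusted over the list alone), with gains in Csrnp1, shared with Ttc21a (3.67 ± 0.17), and in the kinase gene Plk2 (2.84 ± 0.26). Of 12 AP-1 family regions 3 rose and none fell, 4 adjusted over the list alone, and the median was 0.46. They were Maff, shared with Tmem184b (1403 ± 175 against 207 ± 63.5, SD, n = 2, over 17.2 and 6.05 kb), Atf3, shared with Fam71a (7164 ± 487 against 1853 ± 556, SD, n = 2, over 37.5 and 23.9 kb), and Junb, shared with Prdx2 and Rnaseh2a (1.47 ± 0.24). Interferon regions went 4 up and 1 down of 14, 5 and 1 adjusted over the list alone, with gains in Irf1 (3.45 ± 0.21) and in Ifih1, a sensor of viral RNA (4.36 ± 0.30). The camera adjusted p was 1.0e-16 for the NF-kB list, 1.6e-05 for immediate-early, 0.017 for AP-1 and 0.043 for interferon genes. Those calls were lost, at adjusted p = 0.18, 0.18, 0.34 and 0.34 with an estimated correlation. Fry pointed up for all 5 lists, with adjusted p from 8.2e-05 to 0.011.

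The remaining lists did not pass camera. Of 22 macrophage regions 6 rose and 2 fell, 7 and 2 adjusted over the list alone. Tlr2, a receptor of bacterial lipoproteins, rose by 3.27 ± 0.27, and the lysozyme genes Lyz1 and Lyz2 fell from 6862 ± 669.9 to 2378 ± 16.4 (SD, n = 2), over 19.4 and 14.3 kb. The macrophage median was -0.00 and the mean 0.23, and fry pointed up with an adjusted p = 0.015. Idh2, a mitochondrial isocitrate dehydrogenase, fell by 2.50 ± 0.52 and the region of citrate synthase Cs, Coq10a and Ankrd52 by 0.70 ± 0.17. They were the only TCA cycle regions of 22 to fall, and 1 rose. The TCA median was -0.07 and the mean 0.07. Of 19 lysosome and lipid regions 2 rose and 1 fell, Abcg1, a cholesterol exporter (-1.64 ± 0.26), with a median of 0.11 and a mean of -0.00. Of 15 housekeeping regions 3 rose, over Eef1a1 and Mto1 (0.99 ± 0.22), over B2m, Patl2 and Trim69 (0.78 ± 0.18) and over Rplp0 and Gcn1 (0.69 ± 0.18), and fry pointed up with an adjusted p = 0.029, lost with the block (adjusted p = 0.055). None of 6 silent control regions passed. Limma called 3169 of 17081 Pol II regions in GFP cells, 1679 higher and 1490 lower. With the block 6087 passed (3071 higher, 3016 lower), with tags per bp 1225, and without scaling factors, where the median effect was -0.15, 3193 (1300 higher, 1893 lower). Without untreated GFP replicate 1, untreated GFP replicate 2 or GFP LPS replicate 1 the count was 1891, 1683 or 1430.

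In Nur77 cells Acod1 and Cxcl10 were again among the largest gains. Over Acod1 Pol II was 17553 ± 6455 after LPS and 115 ± 11.7 before (SD, n = 2), over 17.5 and 2.09 kb, a log2 change of 7.20 ± 0.33. Over Cxcl10 and Art3 it was 6340 ± 719.7 and 61.5 ± 23.8 (SD, n = 2), over 13.4 and 2.101 kb. The chemokine receptor-like gene Ccrl2 (5.88 ± 0.40), Cd83 (5.80 ± 0.30), Tgm2 (5.18 ± 0.65) and the prostaglandin synthase gene Ptgs2 (4.74 ± 0.57) also rose. Ralgps1 (-4.38 ± 0.48), Dtnb (-4.07 ± 0.36) and Ttc39a (-4.05 ± 0.38) fell.

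Every one of the 12 cytokine and chemokine regions rose in Nur77 cells, as did 24 of 27 NF-kB regions, including Traf1 (4.02 ± 0.20) and Nfkbiz with Nxpe3 (3.33 ± 0.26). Of 23 immediate-early regions 13 rose and none fell, and of 12 AP-1 regions 4 rose and none fell, with Atf3 at 2.39 ± 0.25, Maff at 1.64 ± 0.22 and Junb at 1.39 ± 0.24. These counts were the same adjusted over the list alone. Camera gave an adjusted p = 2.1e-09 for cytokines (adjusted p = 0.040 with an estimated correlation, and 0.17 with the block as well), 2.6e-13 for NF-kB, 3.7e-06 for immediate-early and 0.027 for AP-1 genes. The last 3 calls were lost at adjusted p = 0.19, 0.19 and 0.27 with an estimated correlation, and fry gave 6.7e-05, 0.0021, 0.0025 and 0.011. Interferon regions went 6 up and 2 down of 14, macrophage regions 9 up and 3 down of 22 (11 and 5 adjusted over the list alone) and housekeeping regions 5 up of 15. Camera gave adjusted p = 0.060, 0.060 and 0.052 for these lists, and fry 0.014, 0.0025 and 0.0056. With the block camera passed for the interferon list, at an adjusted p = 0.0496, and gave an adjusted p = 0.36 with an estimated correlation. TCA cycle regions went 1 up and 4 down of 22 (1 and 2 adjusted over the list alone), lysosome regions 4 up and 3 down of 19 (4 and 4) and silent controls 1 up (Gfap, 1.21 ± 0.26) and 1 down (the region of Cd4, Gpr162 and P3h3, -1.39 ± 0.44, but 0.26 with tags per bp) of 6. Limma called 5132 of 17081 Pol II regions, 2465 higher and 2667 lower. With the block 8152 passed (3982 higher, 4170 lower), with tags per bp 2080, and without scaling factors, where the median effect was -0.40, 6080 (1411 higher, 4669 lower). Without untreated Nur77 replicate 1 or 2 the count was 2833 or 2265.

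**Figure D3:**
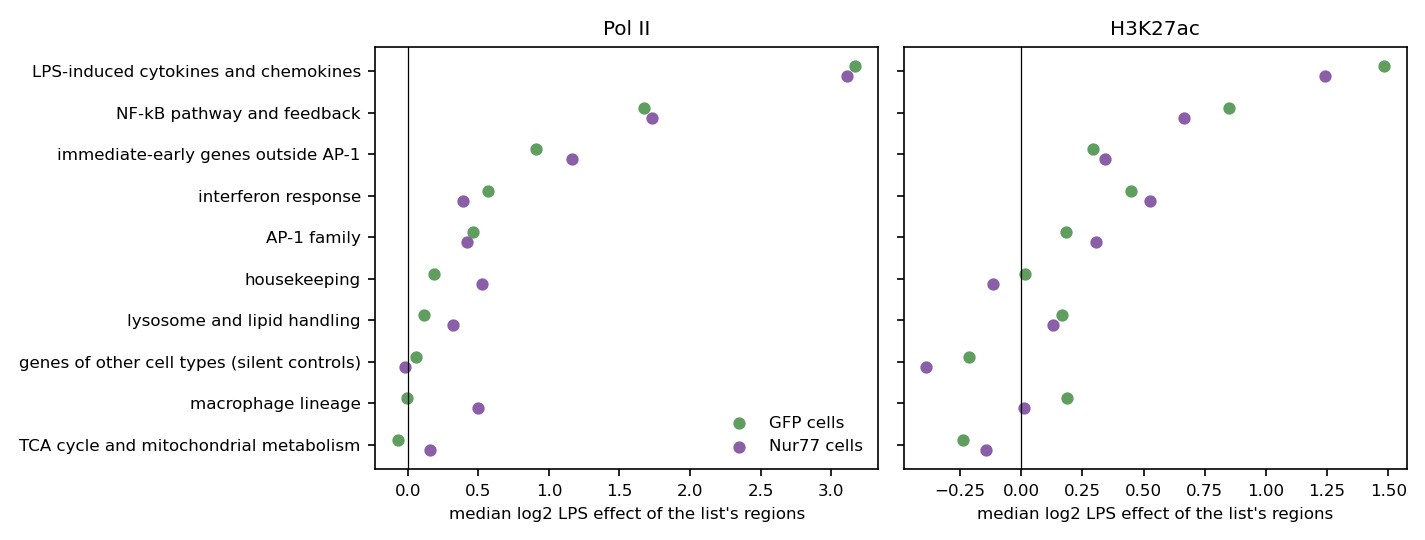
Median log2 LPS effect (x axis) over the tested regions of each gene list (y axis), for Pol II and for H3K27ac. Each point is one line, green for GFP cells and purple for Nur77 cells.

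How did Nur77 cells differ from GFP cells in Pol II? Each construct was in 1 stable line, so this compares the lines as well as the constructs. Before LPS the largest called gains over genes were in Bdp1, which encodes a subunit of a Pol III initiation factor (1296 ± 117 against 133 ± 32.9, SD, n = 2, over 7.60 and 1.63 kb, chr13:100097441-100105385, mm10), and in the neural adhesion gene Cntn4 (1991 ± 229 against 227 ± 19.8, SD, n = 2, over 9.15 and 3.23 kb). The chemokine receptor gene Ccr1 was lower, at 19.3 ± 3.21 against 126 ± 7.15 (SD, n = 2) over 1.05 and 2.12 kb. So was a site 7363 bp from Fos, a founding AP-1 gene, at 463 ± 12.99 against 1232 ± 95.6 (SD, n = 2) over 7.01 and 7.61 kb, which overlapped an input region. No member of any list passed in this comparison. With the block 1 AP-1 region was higher and 2 lower, 1 cytokine region higher and 1 lower, 1 immediate-early region higher and 2 lower and 1 lysosome region higher and 3 lower, and no list passed camera or fry. Adjusted over the list alone, 1 AP-1 region was higher and 2 lower, 1 cytokine region was lower and 1 lysosome region was lower, and no list passed camera or fry. In the AP-1 list the values were 1.08 ± 0.22 for Maff, -0.74 ± 0.22 for Batf and -1.60 ± 0.48 for the region over Fos itself. Limma called 29 of 17081 regions, 19 higher and 10 lower, against 1026 with the block (466 higher, 560 lower), 70 with the block but without untreated Nur77 replicate 1, 50 without scaling factors (median effect 0.18) and 2 with input regions left out. No region passed without untreated Nur77 replicate 1 or 2. The count was 3 without untreated GFP replicate 1, GFP LPS replicate 1 or GFP LPS replicate 2, and 2 without Nur77 LPS replicate 1 or 2.

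After LPS, Basp1 (317 ± 112 against 11.1 ± 0.61, SD, n = 2, over 7.72 and 0.580 kb) and the macrophage lectin gene Clec10a (606 ± 195 against 47.5 ± 14.9, SD, n = 2, over 9.11 and 1.36 kb) were higher in Nur77 cells. Clec2d (-4.54 ± 0.69), Ccr1 (-2.57 ± 0.29) and the lipoprotein lipase gene Lpl (70.3 ± 12.3 against 312 ± 122, SD, n = 2, over 3.13 and 6.28 kb) were lower. Of the list members Lpl was called, 1 of 19 lysosome and lipid regions, and no list passed camera or fry. With the block 2 cytokine, 2 NF-kB, 2 TCA cycle, 1 housekeeping and 1 silent control region were higher and 2 lysosome regions lower. AP-1 and interferon regions then went 1 higher and 1 lower each, immediate-early and macrophage regions 3 higher and 1 lower each, and again no list passed. Adjusted over the list alone, 2 cytokine regions were higher, 1 AP-1 region was higher and 1 lower, 1 immediate-early region was higher and 1 lower, 1 macrophage and 1 silent control region were higher, and 1 interferon and 2 lysosome regions were lower. Limma called 242 of 17081 regions, 132 higher and 110 lower, against 2176 with the block (1048 higher, 1128 lower), 28 with tags per bp, 142 with input regions left out and 1 where only the 4 LPS libraries were fitted. The count was 151 and 128 without untreated GFP replicate 1 or 2, 1 without GFP LPS replicate 1, and 0 without GFP LPS replicate 2 or any one Nur77 library.

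Did LPS act differently on Pol II in the lines? Limma called 0 of 17081 regions for a different LPS effect, with 465 at an unadjusted p below 0.05. The count was also 0 in all other settings, including the block (1391 at an unadjusted p below 0.05) and tags per bp. Among the regions with the smallest p, the LPS gain was smaller in Nur77 cells by 1.32 ± 0.29 log2 for Irf1 and by 1.14 ± 0.32 for Maff, and larger by 1.31 ± 0.39 for Cxcl10, none past the test. No list passed. Camera gave an adjusted p = 0.062 for the macrophage list (median 0.26), and an adjusted p = 0.40 with an estimated correlation. Across regions, which are not independent replicates, the LPS effects of the lines correlated with a Pearson r of 0.91. In both lines 1479 regions rose and 1358 fell, where 242 and 233 would overlap if calls were independent, and 0 moved in opposite directions.

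H3K27ac after LPS in GFP cells rose most at Ccl5, a chemokine gene, with Gm32650 (chr11:83528866-83537482, mm10). It was 220.2 ± 7.79 after LPS and 12.9 ± 0.98 before (SD, n = 2), over 5.01 and 0.946 kb, or 43.9 and 13.6 tags per kb. Acod1 (3.77 ± 0.17), the region of Cxcl10 and Art3 (3.74 ± 0.23), Calcrl (3.73 ± 0.17) and the matrix protease gene Mmp14 (3.55 ± 0.10) followed. Gdpd2 (-3.02 ± 0.27) and Exoc3l2 (-3.01 ± 0.22) fell most.

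By group, 24 of 27 NF-kB regions rose and 1 fell, with Nfkbia, the inhibitor of NF-kB, at 2349 ± 148 against 760.0 ± 13.9 (SD, n = 2) over 8.78 and 8.75 kb and Tnfaip3, another inhibitor, at 1.93 ± 0.07. Of 17 cytokine regions 15 rose and none fell, with a median of 1.48. Of 12 AP-1 regions 6 rose and 4 fell, led by Maff (423 ± 41.8 against 81.2 ± 9.12, SD, n = 2, over 3.81 and 2.84 kb), Atf3 (1.12 ± 0.08) and Junb with Prdx2 and Hook2 (0.93 ± 0.06). Immediate-early regions went 14 up and 5 down of 23 and interferon regions 9 up and 3 down of 16 (10 and 3 adjusted over the list alone). Camera gave adjusted p = 2.3e-11 for NF-kB, 8.3e-09 for cytokine, 0.0093 for immediate-early and 0.042 for interferon genes, all lost with an estimated correlation (adjusted p = 0.11, 0.11, 0.49 and 0.32). Fry gave 5.2e-05, 5.2e-05, 4.2e-04 and 3.0e-04 for these and 0.0046 for AP-1 genes, which did not pass camera (adjusted p = 0.20). TCA cycle regions went 2 up and 10 down of 22 (3 and 11 adjusted over the list alone), among them Idh2 (-1.92 ± 0.23) and Sdhb (-0.94 ± 0.11), and fry pointed down (adjusted p = 0.019). Lysosome regions went 10 up and 5 down of 20 and macrophage regions 11 up and 8 down of 22 (12 and 8 adjusted over the list alone), with Tlr2 at 1.69 ± 0.05 and Cd14, the LPS co-receptor, at 1.03 ± 0.06. Fry pointed up for both (adjusted p = 0.0022 and 0.022). Housekeeping regions went 4 up and 4 down of 15 (median 0.02, mean -0.07), and silent controls 2 up and 3 down of 7, among them Gfap (0.89 ± 0.16) and a site 30026 bp from Nanog (-1.49 ± 0.36).

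In Nur77 cells H3K27ac after LPS gave the following. A site 4164 bp from Manbal (4.52 ± 0.12) and the region of Cxcl10 and Art3 (3.79 ± 0.23) rose, and Gdpd2 (-3.18 ± 0.27) and Kbtbd11 (-2.91 ± 0.14) fell. Of 27 NF-kB regions 24 rose and 2 fell, with Cd83 at 2.28 ± 0.09. Of 17 cytokine regions 15 rose, including the shared region of Ccl3 and Ccl4 (1.21 ± 0.06), and of 12 AP-1 regions 6 rose and 5 fell, with Maff at 1.81 ± 0.10 and Jun, shared with Junos, at -0.59 ± 0.06 (546 ± 7.20 against 824 ± 29.9, SD, n = 2, over 6.65 and 6.85 kb). Immediate-early regions went 13 up and 4 down of 23, with Myc at 2.12 ± 0.13, and interferon regions 10 up and 4 down of 16, with Oasl1 at 1.57 ± 0.07. Camera gave adjusted p = 9.1e-09, 2.5e-08 and 0.023 for NF-kB, cytokine and immediate-early genes, lost at adjusted p = 0.15, 0.15 and 0.61 with an estimated correlation. It gave 0.48 and 0.082 for AP-1 and interferon genes, where fry gave 0.023 and 6.5e-04. Lysosome regions went 8 up and 5 down of 20 (fry adjusted p = 0.020), macrophage regions 10 up and 8 down of 22 (9 down adjusted over the list alone, median 0.01, mean -0.02), TCA cycle regions 4 up and 6 down of 22, housekeeping regions 4 up and 5 down of 15 and silent controls 2 up and 3 down of 7. Limma called 14387 of 27094 regions in GFP cells, 7385 higher and 7002 lower, and 15070 in Nur77 cells, 7596 higher and 7474 lower. Without scaling factors, where the median effects were -0.32 and -0.33, the splits were 4053 higher and 12245 lower, and 4014 higher and 12616 lower.

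Nur77 and GFP cells differed at many H3K27ac regions before LPS. The largest gain in Nur77 cells was 15192 bp from Ccdc25 (chr14:65881796-65885777, mm10), at 195 ± 5.10 against 8.03 ± 0.92 (SD, n = 2) over 3.15 and 0.761 kb. The largest losses were in Foxa1, the gene of a forkhead factor (5.42 ± 0.30 against 91.2 ± 15.2, SD, n = 2, over 0.501 and 2.68 kb), and in Cd84, an immune receptor gene (65.9 ± 6.82 against 798 ± 28.7, SD, n = 2, over 3.75 and 13.3 kb). Of 12 AP-1 regions 5 were higher and 3 lower. Fos (-0.95 ± 0.10), Batf (-0.74 ± 0.08) and Atf3 (-0.77 ± 0.08) were the lower ones, though with tags per bp Atf3 did not pass (-0.21, adjusted p = 0.33). Of 23 immediate-early regions 8 were higher and 6 lower, among them Klf2 (474 ± 5.66 against 204 ± 17.9, SD, n = 2, over 7.23 and 5.64 kb), Egr1 (0.70 ± 0.08) and Rhob (-0.78 ± 0.07). Of 27 NF-kB regions 10 were higher and 2 lower, with Socs3 at 0.68 ± 0.08 and Cd83 at -1.06 ± 0.09. Of 17 cytokine regions 7 were higher and 4 lower, with Il27 at 1.22 ± 0.08 and the interleukin-1 antagonist gene Il1rn at -1.12 ± 0.08. Of 20 lysosome and lipid regions 6 were higher and 7 lower, with Npc2, a cholesterol carrier, shared with Isca2 (-0.75 ± 0.05), and Gpnmb (-0.64 ± 0.06). Fry pointed down for that list (adjusted p = 0.011). TCA cycle regions went 0 higher and 5 lower of 22, macrophage regions 2 and 4 of 22, interferon regions 2 and 0 of 16, housekeeping regions 2 and 1 of 15 and silent controls 1 and 1 of 7. Adjusted over the list alone the counts were 9 and 7 for immediate-early, 11 and 2 for NF-kB, 9 and 4 for cytokine, 6 and 10 for lysosome, 0 and 3 for TCA cycle and 4 and 10 for macrophage regions. Signs differed between median and mean for the immediate-early (-0.01 and 0.07), housekeeping (-0.02 and 0.02) and silent control regions (0.12 and -0.06), and fry pointed down for AP-1 genes where camera pointed up. No list passed camera. Limma called 8344 of 27094 regions, 4300 higher and 4044 lower, against 3821 with tags per bp. Without untreated Nur77 replicate 1 or 2 the count was 5541 or 5325.

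After LPS the lines also differed. Foxa1 (-4.30 ± 0.22) and Cd84 (-3.32 ± 0.10) were again lower in Nur77 cells and the site near Ccdc25 (4.10 ± 0.19) again higher. Lpl was lower, at 104 ± 14.7 against 367 ± 2.79 (SD, n = 2) over 4.36 and 9.21 kb. Of 12 AP-1 regions 2 were higher and 5 lower, with Batf at -0.97 ± 0.08, Jund, shared with Iqcn, at -0.73 ± 0.08 and Atf3 at -0.62 ± 0.08. Of 27 NF-kB regions 3 were higher and 8 lower (4 and 8 adjusted over the list alone), with Nfkbia at 1414 ± 2.05 against 2349 ± 148 (SD, n = 2) over 7.83 and 8.78 kb and Tnfaip2 with Exoc3l4 at -0.74 ± 0.06. Of 23 immediate-early regions 6 were higher and 9 lower, with Rhob at -1.26 ± 0.07, the DNA damage gene Gadd45b at -0.86 ± 0.09 and Egr1 at 0.71 ± 0.08. Of 22 macrophage regions 2 were higher and 8 lower, with the myeloid factor gene Cebpa at -1.04 ± 0.13, and of 20 lysosome and lipid regions 2 were higher and 10 lower (3 and 10 adjusted over the list alone). Fry pointed down for lysosome (adjusted p = 0.0038), AP-1, NF-kB and macrophage genes (0.048 each), and no list passed camera. Cytokine regions went 6 higher and 4 lower of 17 (7 and 4 adjusted over the list alone; median 0.17, mean -0.08), interferon regions 3 and 3 of 16, with Oasl1 at 0.88 ± 0.07 and Irf1 at -0.69 ± 0.09, TCA cycle regions 1 and 2 of 22, housekeeping regions 3 and 3 of 15 and silent controls 1 and 1 of 7. For the TCA cycle, silent control, housekeeping and interferon lists the median and mean were below 0 while camera pointed up. Limma called 9767 of 27094 regions, 4553 higher and 5214 lower, against 4578 with tags per bp.

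The interaction asked whether the LPS effect on H3K27ac itself differed. The LPS gain was smaller in Nur77 cells at Irf1 (by 1.08 ± 0.12 log2, though with tags per bp the change in GFP cells turned to -0.14), at Csrnp1 (by 0.88 ± 0.09), at Nfkbia (by 0.62 ± 0.08) and at Gadd45b (by 0.65 ± 0.12), and the difference was also negative at Klf2 (-0.92 ± 0.13), Jund (-0.63 ± 0.11), Lpl (-1.06 ± 0.15) and Spi1, the gene of the myeloid factor PU.1 (-0.56 ± 0.10). It was positive at Gm40121 (2.00 ± 0.19), where it turned to -0.25 with tags per bp. Of 27 NF-kB regions 1 passed and was lower, 11 were lower adjusted over the list alone, and the median difference was -0.19. Camera gave an adjusted p = 2.0e-05, lost at an adjusted p = 0.64 with an estimated correlation, and fry gave an adjusted p = 0.095. Of 12 AP-1 regions 1 was lower (1 higher and 5 lower adjusted over the list alone), and of 23 immediate-early regions 3 were lower (1 higher and 7 lower). One region each was lower among interferon, lysosome and macrophage genes, where the counts adjusted over the list alone were 1 higher and 1 lower, 1 and 1, and 2 and 2. None passed among cytokine (2 lower adjusted over the list alone), TCA cycle, housekeeping and silent control genes, and none of these 9 lists passed camera or fry. Limma called 184 of 27094 regions, 35 higher and 149 lower, against 68 without scaling factors, 0 with tags per bp (2567 at an unadjusted p below 0.05), 42 with the peak-calling option as a term and 124 with input regions left out. Left-out libraries gave 39 and 16 (untreated GFP replicates 1 and 2), 36 (GFP LPS replicate 1), 19 and 1 (untreated Nur77 replicates 1 and 2) and 26 (Nur77 LPS replicate 1), so the calls at Jund and Gadd45b held in 1 of 8 such fits, those at Nfkbia, Klf2 and Lpl in 4, and those at Irf1 and Csrnp1 in 7.

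The gene Nr4a1, which encodes Nur77, had weak signal at all its tested regions. In the Pol II region at chr15:101265756-101267711 (mm10), signal in Nur77 cells was 54.7 ± 23.5 after LPS and 13.3 ± 2.21 before (SD, n = 2), over 1.44 and 0.891 kb (1.90 ± 0.48, adjusted p = 0.020). That call held in 5 of 8 fits with a library left out and was lost with tags per bp (adjusted p = 0.11). In H3K27ac, the region at chr15:101261782-101263593 (mm10) was higher in Nur77 cells after LPS, at 28.3 ± 4.87 against 13.7 ± 7.48 (SD, n = 2) over 1.13 and 0.899 kb (adjusted p = 0.021), in 6 of 8 such fits. In GFP cells it fell after LPS by 0.89 ± 0.32 log2 (adjusted p = 0.035), in 3 of 8. The labels do not give the transgene sequence, so these values do not check which cells carried it.

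Called regions were also compared between conditions. For Pol II, 1996 regions were called in both GFP replicates after LPS and in neither before it, and 1628 the other way round. In Nur77 cells the counts, made in the same way, were 1789 and 1210. For H3K27ac they were 1910 and 3154 in GFP cells and 2336 and 3585 in Nur77 cells. Splitting the same libraries by replicate number gave 790 and 1115 (GFP) and 95 and 1194 (Nur77) for Pol II, and 394 and 953, and 884 and 739 for H3K27ac. The 1210 Pol II regions called only before LPS in Nur77 cells were thus hardly more than the 1194 of the replicate split, and numbered 782 with an overlap of 50%. The strongest Pol II region of GFP cells called after LPS only spanned Ccl5, Heatr9, Gm32650 and Gm23247 (6969 ± 4164, SD, n = 2, over 17.4 kb), and that of Nur77 cells covered Cybb, a subunit of the phagocyte oxidase (846 ± 106, SD, n = 2, over 12.7 kb). The HA site gained in Nfkb1 lay in an H3K27ac region called after LPS only in GFP (157 ± 16.7, SD, n = 2) and in Nur77 cells (180.4 ± 9.12, SD, n = 2). Between the lines, 287 Pol II regions before LPS and 532 after it were called in Nur77 cells only, and 1586 and 1880 in GFP cells only. For H3K27ac these were 3070 and 3016 in Nur77 cells and 2445 and 2252 in GFP cells. With lists of equal length the order of the lines turned, at 2543 and 2323 in Nur77 cells and 2628 and 2608 in GFP cells. Replicate number gave 73 and 2094 before LPS and 469 and 1022 after it for Pol II. For H3K27ac it gave 550 and 823 before LPS, and 649 and 875 after it. Of the Pol II counts between the lines only the 1880 regions of GFP cells after LPS thus exceeded the larger replicate count. With lists of equal length they numbered 1019, but the replicate split was made with full lists only. The strongest Pol II region called in Nur77 cells only was in Chd2, a chromatin remodeller gene, at 1430.5 ± 599.7 before and 3866 ± 852 after LPS (SD, n = 2), over 5.17 and 4.50 kb.

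The series title speaks of direct and indirect control by Nur77, so regions with and without an HA peak were compared. H3K27ac regions that met an HA region called after LPS only (699 against 26395 others) gained H3K27ac with LPS in Nur77 cells, with a median log2 change of 0.59, and 59.9% rose while 10.4% fell. In GFP cells, which lack HA-Nur77, the same regions had a median of 0.62, and 61.2% rose while 9.01% fell. Camera gave adjusted p = 5.2e-12 in Nur77 and 9.9e-14 in GFP cells, and an adjusted p = 0.0060 with an estimated correlation in each. Pol II behaved alike at 421 such regions, with medians of 0.43 in Nur77 and 0.36 in GFP cells and adjusted p = 7.1e-08 and 1.9e-09, or 0.0060 with an estimated correlation in each. Without scaling factors all of these calls were lost with an estimated correlation, at adjusted p = 0.21 for each line and assay. The difference between the lines at these regions did not pass camera for either assay before or after LPS (adjusted p from 0.31 to 0.96). Fry passed only for H3K27ac after LPS, where the regions were lower on balance in Nur77 cells (adjusted p = 0.0047). Among the 359 changed HA regions that overlapped a tested H3K27ac region, 349 had the same sign as the H3K27ac effect in GFP cells and 347 in Nur77 cells, whether or not H3K27ac passed. In GFP cells 259 passed as higher and 65 as lower in both, where 105 and 23.6 would if calls were independent, and in Nur77 cells 252 and 75, where 101 and 25.6 would.

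**Figure D4:**
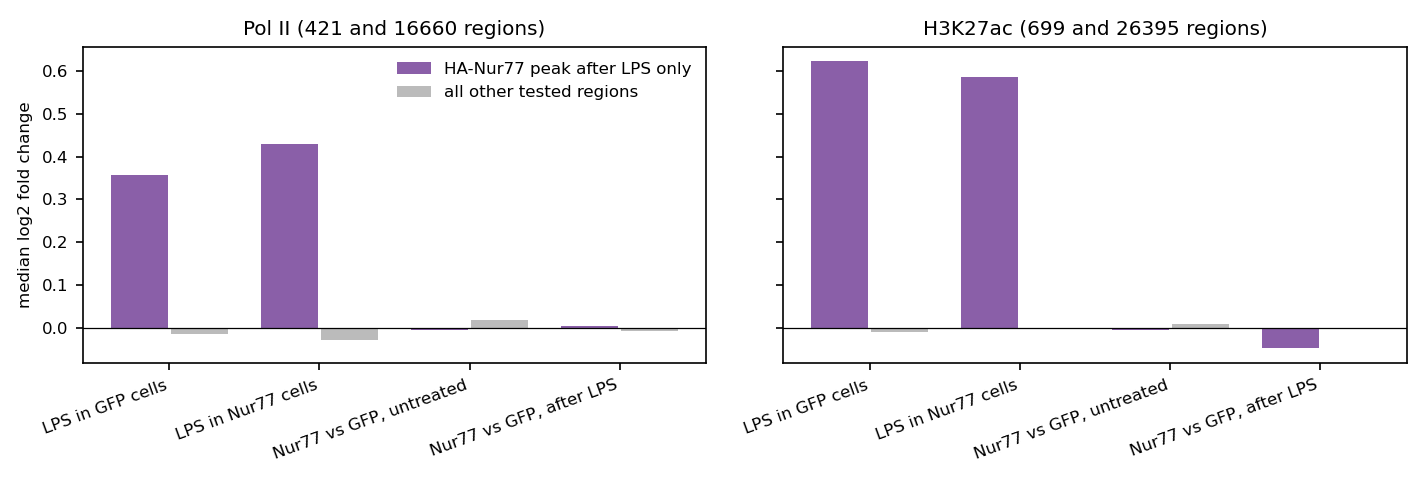
Median log2 fold change (y axis) of Pol II and H3K27ac regions that overlap an HA-Nur77 region called after LPS only (purple bars) and of all other tested regions (grey bars), for each comparison on the x axis. Bars are medians over regions of the fitted effects of 8 libraries per assay.

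The lines were also compared at regions with an HA peak in all 3 untreated libraries. Their median H3K27ac difference before LPS was 0.07, against -0.03 at regions of like signal outside that set. Of the 9785 H3K27ac regions with an HA peak before LPS, 25.3% were higher in untreated Nur77 cells and 16.01% lower. Regions of like signal outside that set, some with an HA peak in fewer libraries, gave 11.2% and 16.7%. Camera gave an adjusted p = 0.020 and an adjusted p = 0.13 with an estimated correlation, and fry an adjusted p = 0.0049. After LPS 24.2% of the same regions were higher in Nur77 cells and 21.2% lower, against 12.5% and 23.0% outside the set. For Pol II the medians were 0.08 at such regions and -0.02 at all others before LPS. Camera gave an adjusted p = 0.012, lost at an adjusted p = 0.15 with an estimated correlation, and fry an adjusted p = 0.12. With an estimated correlation camera passed for the 14004 Pol II regions that met an HA peak in any library. The adjusted p was 0.029 for the lines before and after LPS, lost without scaling factors (adjusted p = 0.95). Fry did not pass for these regions (adjusted p = 0.16 before and 0.53 after LPS). At the preset correlation only Pol II comparisons passed camera with this set, and those of H3K27ac did not. Across regions, which are not independent replicates, the difference between the lines before and after LPS correlated with a Pearson r of 0.80 for H3K27ac and 0.70 for Pol II. Of the 8344 H3K27ac regions called before LPS, 2876 were also called higher and 3024 lower after it, where 723 and 778 would be shared if calls were independent, and 45 changed sides. H3K27ac and Pol II effects correlated with a Pearson r of 0.82 for LPS in GFP cells, 0.83 for LPS in Nur77 cells, 0.71 for the lines before LPS, 0.69 for the lines after LPS and 0.40 for the interaction, across 16648 regions.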

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

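The tests of length, scaling, HA binding and separate lines for the first pattern, of the need for HA-Nur77 and of the HA antibody for the second, and of scaling, correlation and Pol II for the third were chosen after the result was seen. So was the test of sites called in one line only. The other tests were set before.

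The LPS effect on H3K27ac differed between the lines at 184 regions, and the largest differences lay outside the lists. Log2 differences were positive for Fbxw7 (2.24), Nufip2 (2.21), Amn1 (2.02), Gm40121 (2.00), Dock10 (1.97), near Cenpw (1.78), Pcdh7 (1.67), near Efcab11 (1.47), near Manbal (1.09) and Pum2 (1.01). They were negative for Stt3b (-2.48), Gm46565 (-1.86), Bbs9 (-1.64), A530072M11Rik (-1.61), Tspan18 (-1.55), Nfatc1 (-1.38), Cd101 (-1.37), Calcrl (-1.36), Pdgfa (-1.35) and Git2 (-1.33). Among list members they were negative for Jund (-0.63), Nfkbia (-0.62), Csrnp1 (-0.88), Klf2 (-0.92), Gadd45b (-0.65), Irf1 (-1.08), Lpl (-1.06) and Spi1 (-0.56). The NF-kB list had a median difference of -0.19. With tags per bp none of these regions passed, and the sign turned for Amn1, Gm40121, Dock10, near Cenpw, near Efcab11, Pum2, Bbs9, A530072M11Rik and Calcrl.

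The wide H3K27ac difference between untreated Nur77 and GFP cells, including Cd84, Foxa1 and Klf2, held its sign with tags per bp at 92.8% of called regions, which argues against region length as the source of its direction. How much of its size is due to length stays open, as the median log2 difference was 0.67 and with tags per bp 0.33, and 3300 of 8344 regions stayed called. Without scaling factors 90.8% were called the same way, 95.4% had the same sign in the LPS libraries and 90.2% of those over a Pol II region had the same sign in Pol II. Regions bound before LPS were called higher by 14.1 points more than other regions of like signal. HA was mapped in Nur77 cells only, so this excess cannot tell an effect of HA-Nur77 binding from regions that were stronger in that line. Regions bound after LPS only had an excess of 8.47 points before LPS and of 4.81 points after it. Their excess was taken over regions with no HA peak in any library, so it does not compare directly with the 14.1 points. Binding is left open, and separate origin of the lines could not be told apart from it, with 1 line per construct.

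Regions with HA peaks after LPS only gained H3K27ac in both lines. A need for HA-Nur77 is argued against by the ratio of the median gain in GFP to that in Nur77 cells, 1.06. Region length and signal level are argued against by a median gain in GFP cells of 0.35 with tags per bp and of 0.66 above unbound regions of like signal. HA antibody signal that follows open chromatin may also play a part and could not be told apart, with 0 HA libraries of GFP cells. Endogenous Nr4a1 in GFP cells is not excluded.

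The smaller H3K27ac gain at NF-kB genes in Nur77 cells kept its direction without scaling factors (-0.21), with the peak-calling option as a term (-0.17) and with any one library left out (at most -0.14), which argues against scaling, the option or a single library. The median difference between the lines was 0.15 before LPS and -0.07 after it, and neither passed camera. Region length could not be told apart, with a median of -0.13 with tags per bp. Genes moving together could not be told apart either, with an adjusted p of 0.639 with an estimated correlation in limma's camera. Less transcription could not be told apart, though the Pol II median difference was 0.10, towards a larger LPS effect in Nur77 cells. Of 27 Pol II regions 11 had a smaller effect. That median lay within its SD of 0.12 over the fits with 1 library left out.

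Sites called in one line only met in Pol II and H3K27ac at least 23.3 times as often as the product of their shares, which argues against independent calls. The product took no account of signal level. For the LPS effect on HA-Nur77 the 10 splits of the 6 libraries are too few for a share under 0.05, and the real split, which was 1 of 10 with that many, gave 520 regions while the highest other gave 0. Splits that part as many replicate pairs also gave 0.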

How the results depend on the processing

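The runs with both replicate 3 HA libraries left out, with the peak-calling option as a term, with another pseudocount, with median-ratio scaling, with gene ends only, with tags per bp for list members and with the block but without untreated Nur77 Pol II replicate 1 were added after the files had been seen. Values are given in the order of the results in the report, and the cause of each change was not tested. HA regions changed by LPS numbered 520, against 6 without scaling factors, 4552 with the replicate block, 0 without both replicate 3 libraries and 4046 without them but with the block, and ran from 0 to 628 with one library left out. Pol II regions changed by LPS in GFP cells numbered 6087 with the block, 1225 with tags per bp and 5622 with the block but without untreated Nur77 replicate 1 (1430 to 3197 with one library left out), and in Nur77 cells 8152 and 2080 (2265 to 5116). Pol II regions that differed between untreated lines numbered 50 without scaling factors, 1026 with the block, 2 with input regions left out, 4 with only the 4 libraries compared and 70 with the block but without untreated Nur77 replicate 1 (0 to 26). After LPS the counts were 2176 with the block, 28 with tags per bp, 142 with input regions left out, 1 with only the 4 libraries and 1654 with the block but without that library (0 to 151). H3K27ac regions changed by LPS ran from 11324 to 15126 in GFP and from 11874 to 15394 in Nur77 cells. Those that differed between lines numbered 3821 with tags per bp before LPS (5325 to 9035) and 4578 after it (7585 to 9405). The H3K27ac interaction count was 68 without scaling factors, 0 with tags per bp and 42 with the option as a term (1 to 185), and 193 with the block, although H3K27ac deviations did not pair by replicate number (-0.10 to 0.09). The block changed no other H3K27ac count by more than a few percent. HA regions called after LPS only numbered 1081 with equal list lengths, 4489 with 2 of 3 replicates and 3378 without both replicate 3 libraries (2315 to 3325), and those called before LPS only 589, 1106 and 641 (379 to 766). With 1 of 2 replicates, Pol II regions called in one condition only numbered 7277 and 6702 in GFP cells (1996 to 4900 and 1628 to 4699) and 6114 and 6968 in Nur77 cells (1789 to 4673 and 1210 to 5855), the last of which was 782 with an overlap of 50%. Between lines they numbered 4185 and 7279 before LPS (287 to 3120 and 1586 to 4580) and 3443 and 7966 after it (532 to 2569 and 1880 to 5273), and with equal list lengths 572, 1035, 852 and 1019. For H3K27ac they numbered 8923 and 11486 in GFP cells (1910 to 5608 and 3154 to 8738), 12677 and 13011 in Nur77 cells (2336 to 7628 and 3585 to 9009), 12888 and 9496 between untreated lines (3070 to 8681 and 2445 to 7210) and 14774 and 9153 after LPS (3016 to 9117 and 2252 to 5879). No gene list passed camera with an estimated correlation and the block (0), 382 list members were called with tags per bp, and 4 of the bound-region tests passed with a peak in any library, all of them for Pol II. With tags per bp the sign reversed for H3K27ac after LPS in GFP cells at Naa25 (0.063) and Irf1 (-0.14), between lines at Ogdh after LPS (-0.19) and at Irf1 before it (-0.031), and in the interaction at Amn1 (-0.0012), Gm40121 (-0.25), Dock10 (-0.11), near Cenpw (-0.36), near Efcab11 (-0.90), at Pum2 (-0.12), Bbs9 (0.32), A530072M11Rik (0.0059) and Calcrl (0.13). It also reversed for Pol II after LPS in Nur77 cells at Cd4 (0.26), Rplp0 (-0.0023) and Fcgr3 (0.10), and between lines after LPS at Slc30a1 (0.063). Without scaling factors it reversed for H3K27ac after LPS in GFP cells at Gusb (-0.046). Count-based tools and the motif test were not run. Where a left-out library leaves a lone sample in its group, that group was assumed to vary like the others. With 2 Pol II libraries per group, and 3 HA libraries per condition at 6.41 to 18.2 M tags, small changes in Pol II and HA remain unresolved.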

Other observations

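The tests of line-only sites and of the Chd2 site were chosen after the result was seen.

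Sites called in one line only were shared between assays. In Nur77 cells 81 Pol II and 605 H3K27ac sites were called in all libraries of the line and in none of the GFP line. Of these 28 were in both assays, where 0.371 would be if calls were independent. They included Zic5, a neural crest factor gene, with a Pol II mean of 246 and an H3K27ac mean of 117 (n = 4), a site near Vmn1r61 (250 and 131) and Arhgef33 (189 and 64.3). In GFP cells 328 and 595 sites gave 60 in both, where 2.57 would be if calls were independent, including Prkg2, a cGMP-dependent kinase gene (123 and 89.8). The expected counts took no account of signal level. Of the H3K27ac sites 22.0% in Nur77 and 8.74% in GFP cells met an HA peak. HA was mapped in Nur77 cells only, so these shares do not compare the lines. Of the 27094 tested H3K27ac regions, which had a peak in every library, 11744 met an HA region called after LPS.

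The Pol II site in Chd2 (chr7:73509962-73515456, mm10) was called in no GFP library. The H3K27ac region that overlaps it (chr7:73510458-73519654) had peaks in both lines, at 64.9 to 128. That region runs past the Pol II site, so peaks of single libraries may lie outside the site. An HA peak lay within the Pol II site in 5 of 6 libraries, and input had none there.

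Separate origin of the lines is a candidate explanation for the line-only sites, as both lines had their own. The ratio of shared to expected sites, 75.5 in Nur77 and 23.3 in GFP cells, does not tell it from an effect of the construct. At the regions with HA peaks after LPS only, the median H3K27ac gain in GFP cells was 1.06 times that in Nur77 cells. The gain was thus also present without HA-Nur77. Whether LPS opened these regions to HA-Nur77 cannot be told, as open chromatin and the order of events were not measured. An HA ChIP of GFP cells would check the HA background, and a second clone per construct would help tell separate origin from the construct.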
